A study of Arabidopsis thaliana with 8 samples.

How the data were processed

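The series measured transcript levels in 8 array samples of wild-type Arabidopsis thaliana, accession Columbia 0. Total RNA of plants aged 3 weeks was compared with total RNA of plants aged 4 weeks, with 4 arrays per age numbered 1 to 4 in the labels. The organ sampled, the growth conditions, the array type, the RNA label and the scanner are not given in the sources used here. Each sample is called an array here, since the labels do not say whether samples of both ages shared an array. Nor do the labels say whether the 4 arrays of an age came from separate plants. The p-values therefore measure only the spread between these samples, which may be technical.

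The authors deposited 1 table of array intensity values on a linear scale, with 3439 probes and 1 column per sample. Upstream steps are not stated. From the values, the deposited intensities run from 0 to a ceiling just under 100 that several probes of every array share, so a scaling and a lower bound at 0 were applied before deposit. The factor of that scaling, any background correction and the label stay unknown. The array medians of the deposited values were 0.0239, 0.0255, 0.0296 and 0.0308 at 3 weeks and 0.440, 0.445, 0.390 and 0.397 at 4 weeks, in the order of the replicate numbers. The table was therefore not on a common distribution, and a level read from it depends on how the arrays are scaled. Values of 0 made up 26.9% to 32% of the probes of a 3-week array and 13.4% to 13.7% of those of a 4-week array. A probe listed at 0 has no known level, and 6 probes on all 4 arrays of 3 weeks and 3 on all 4 arrays of 4 weeks sat at the ceiling, where only a bound is known. Signal over background could not be computed, and the number of arrays limits the precision.

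Gene names came from the platform annotation that pairs probes with genes. Of the 3439 probes, 692 had 1 gene, 870 had several and 1877 are unnamed here. No gene was named from a probe with several. Symbols were updated through the Entrez gene number with a RefSeq table of assembly TAIR10.1, which held 690 of the 692 and gave 92 a symbol other than the locus code. No genome build goes with the arrays, and no coordinates are given. Unnamed probes stayed in the test, because nothing in the sources marks them as controls or as lacking a gene.

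The intensities were brought to a common distribution by quantile normalization between arrays, raised to a floor and converted to log2. A floor at percentile 5 of each array had been fixed before the data were examined, with percentiles 1 and 10 as alternatives. All 3 percentiles are 0 on every array and have no logarithm. The floor used instead was the normalized intensity at rank 1099, the number of zeros on the array with most of them, which is 0.123. It left 1388 probes above the floor on all 8 arrays. Values at the floor have no order. A log2 difference is the mean at 4 weeks minus the mean at 3 weeks on this scale, so it is a change relative to the other probes of the array and understates changes of probes near the floor. "Rose" and "fell" are used in that sense, and a gene can fall in that sense while its deposited intensity is higher at 4 weeks. Deposited intensities are given as mean ± SD over 4 arrays.

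Each probe was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the 3439 probes and a threshold of 0.05. The fit held age alone. Gene lists were tested with limma camera at a preset inter-gene correlation of 0.01, beside camera with an estimated correlation and fry, for lists with at least 5 measured genes. Before the data were examined, 20 lists had been fixed by locus and 10 by a word in the gene name or a locus prefix. The words were matched against symbols and synonyms, since no gene descriptions were used here. The pentatricopeptide list at first took in LAS through letters inside "suppressor", and the match was then made sensitive to case. A list of photosynthesis genes, which merges 5 of the fixed lists and holds only their members, was added after the data were seen. No list gene had more than 1 probe, so averaging the probes of a gene, an alternative fixed beforehand, changes nothing.

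The named genes were chosen by a rule fixed before the data were examined. It took the probes with 1 gene past the threshold whose 4 values at one age all lay above the 4 at the other, and named the 12 with the largest increase and the 12 with the largest decrease. It also named, within each list of at least 5 measured genes, the 2 with the smallest p and the 2 with the largest difference. Because values at the floor or ceiling cannot be ranked, the 24 were taken from probes above the floor on all 8 arrays and below the ceiling, a restriction added after the data were seen. Members of smaller lists and the genes of the closing section were named after their values were seen.

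The replicate numbers were checked for pairing before any calls were compared. Deviations from the age means, over all probes, correlated at 0.17, 0.21, 0.17 and 0.24 between the arrays of both ages with the same number, and all 4 arrays of 3 weeks correlated best with their own number. The numbers may therefore pair the samples, which is read from the data and not from the labels. Replicates 1 and 2, and 3 and 4, also went together at both ages, and the pairing by number was not tested apart from that. A fit with the number as a block was run as an alternative. Other alternatives were no normalization between arrays, scaling to a common median, cyclic loess, a filter on dim probes, other variance priors, array weights, and leaving out each array in turn. Added after the data were seen were an estimated correlation in camera under each other scaling, a floor at the median probe, only probes above 0 on all arrays, leaving out probe numbers that are multiples of 6, and 4 fits that treat replicates 1 and 2 apart from 3 and 4.

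The fit was tested on simulated data of 3439 probes built for the comparison of 4 with 3 weeks. It recovered 44 of 50 probes changed by -2 on the log2 scale, 35 of 50 changed by -1, 39 of 50 changed by 1 and 47 of 50 changed by 2. Of 3239 unchanged probes it called 22. The changed probes were drawn from above the median level, as many up as down, with noise independent between arrays. In the data 56.6% of the probes passed and some replicates resemble each other more than others. The rates describe the fit in the simulated setting and not its error in these data.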

Results

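Total RNA from wild-type Columbia 0 plants, a standard laboratory accession of Arabidopsis, gave 8 hybridised samples, called arrays here. Of these, 4 came from plants aged 3 weeks and 4 from plants aged 4 weeks. The deposited intensities summed to 2882 to 3084 per array at 3 weeks and 3176 to 3359 at 4 weeks. Their distributions had different shapes. The 100 brightest probes held 81.8% of the mean summed intensity at 3 weeks and 45.4% at 4 weeks, and the mean of the array medians was 15.2 times as high at 4 weeks. Spearman correlations across the 3439 probes ran from 0.845 to 0.885 between arrays of 3 weeks, from 0.920 to 0.974 between arrays of 4 weeks and from 0.413 to 0.459 between arrays of different age. Probes are not independent replicates, so these values only describe the arrays.

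**Figure D1:**
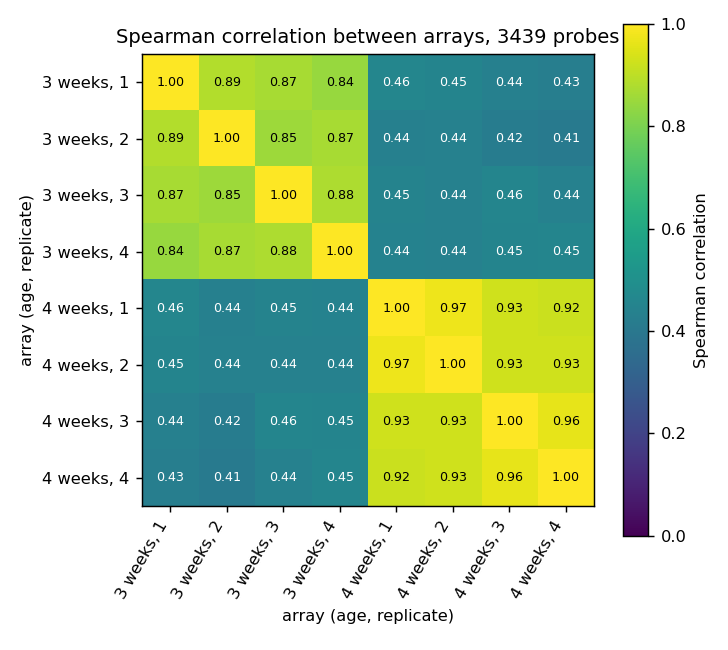
Spearman correlation (colour and printed value, no unit) between each pair of the 8 arrays over 3439 probes, with the arrays labelled by age and replicate on both axes. Pairs of the same age lie at 0.845 or above and pairs of different age at 0.459 or below.

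The comparison asked which transcripts differ between plants of 3 and of 4 weeks. PRK and PSAN, of photosynthesis, were among the 12 largest decreases at 4 weeks of genes above the floor on all 8 arrays. PSBW of photosystem II rose, a direction that turned under median scaling. The 6 measured genes of the merged photosynthesis list did not stand apart as a set after quantile normalization (camera adjusted p = 0.105) or cyclic loess (0.873). They did without scaling (7.06e-05) and under median scaling (0.00436). With an estimated correlation the adjusted p was 0.233 after quantile normalization, 0.884 under cyclic loess, 0.0444 without scaling and 0.192 under median scaling, where the call was lost. Lower values at 4 weeks were common among bright probes, with 92 of the 100 brightest at 3 weeks lower in deposited mean. The probe for PRK, the phosphoribulokinase of the Calvin cycle, went from an intensity of 7.23 ± 1.45 (SD, n = 4) at 3 weeks to 0.951 ± 0.13 at 4 weeks, and PSAN, a subunit of photosystem I, from 19.2 ± 1.62 to 2.54 ± 0.333. Among genes above the floor on all 8 arrays the largest log2 increase after quantile normalization was that of AT4G31530, from 1.48 ± 0.1 to 25.9 ± 2.55, a call lost under median scaling (0.19, adjusted p = 0.382). AT1G16080 went from 0.36 ± 0.0382 to 11.3 ± 0.547 and AILP1 from 0.0354 ± 0.0144 to 2.71 ± 0.203.

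In limma's test 1946 of the 3439 probes (56.6%) passed a Benjamini-Hochberg adjusted p of 0.05, 1004 of them higher and 942 lower at 4 weeks. A difference of at least 2-fold was met by 661 of the higher and 638 of the lower probes. Of the 692 probes with 1 gene, 368 passed, with 215 higher and 153 lower. The split between higher and lower depends on the scaling. It was 1710 higher and 263 lower when the deposited intensities were raised to a floor without scaling between arrays. After scaling to a common median it was 688 higher and 1160 lower. Differences without scaling are bounded by that floor. The median log2 difference over all probes was 0.408 without scaling, and 1299 probes, 810 higher and 489 lower, were past the threshold after quantile normalization and kept their direction under no scaling, median scaling and cyclic loess. At both ages replicates 1 and 2 resembled each other more than they did 3 and 4. The test gave 1690 probes within replicates 1 and 2 alone and 1687 within replicates 3 and 4 alone.

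**Figure D2:**
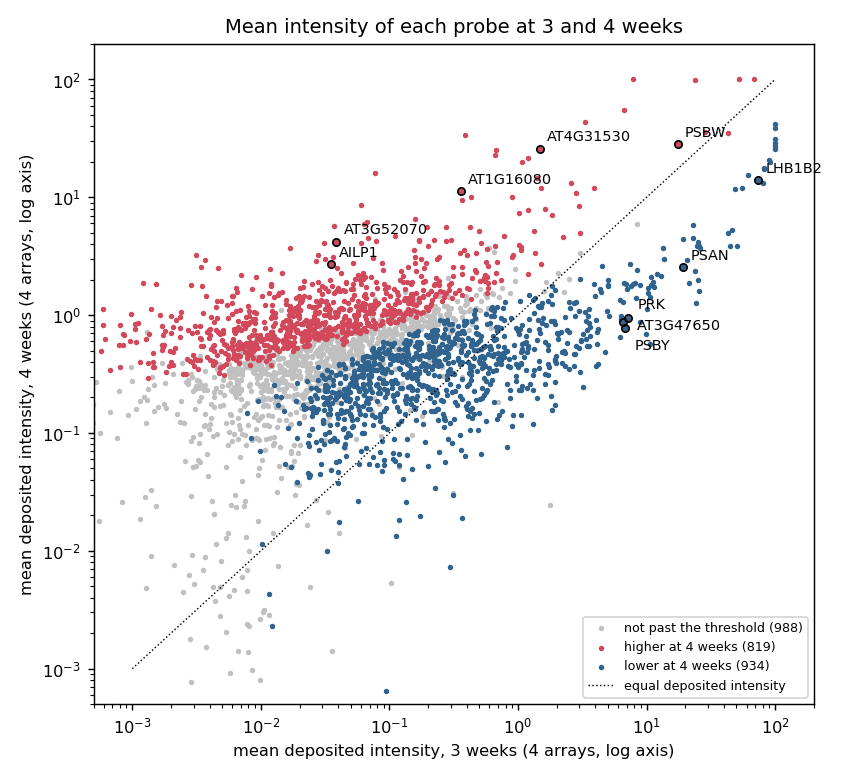
Mean deposited intensity of each probe at 3 weeks (horizontal) and 4 weeks (vertical) over 4 arrays each, in arbitrary units on log axes, for the 2741 probes with a mean above 0 at both ages; the dotted line marks equal intensity. Red marks the 819 of these probes that limma called higher at 4 weeks and blue the 934 called lower, after quantile normalization, which is why many blue points lie above the line; named genes are circled.

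Among the 12 named increases, 3 genes were dim at 3 weeks, though their mean intensities lay above the medians of the 3-week arrays (0.0239 to 0.0308). AT3G52070 went from 0.0386 ± 0.0258 to 4.2 ± 0.445, a log2 difference after normalization of 4.36 (SE 0.26). AT1G01730 went from 0.0522 ± 0.00684 to 2.77 ± 0.247, and AILP1 rose by 3.48 (SE 0.14) after normalization. AT2G36480 went from 0.158 ± 0.0106 to 6.52 ± 0.54 and AT4G20300 from 0.157 ± 0.0542 to 3.12 ± 0.351. AT1G13370, which encodes a histone of the H3 type, went from 0.893 ± 0.0709 to 10.1 ± 1.42, a log2 difference of 3.33 (SE 0.12). After quantile normalization AT4G19900, AT5G38310 and AT2G27290 rose by 2.99, 2.97 and 2.78 on the log2 scale. The adjusted p-values of AT4G31530 and AT1G16080 were 4.31e-08 and 1.65e-08. The widest error was that of AT4G17070, with 1.51 ± 0.963 at 3 weeks and 12.1 ± 8.17 at 4 weeks, a log2 difference of 3.14 (SE 0.69) and an adjusted p of 0.00648, which became 0.123 when replicates 1 and 2, and 3 and 4, were averaged first. All 12 were higher at 4 weeks in the deposited intensities on every array. Of all 3439 probes, 2680 had a higher deposited mean at 4 weeks, so this adds little. Under every scaling 8 of the 12 kept their direction. Of these, AT4G31530, AT5G38310 and AT4G20300 did not pass in limma after scaling to a common median (adjusted p = 0.382, 0.93 and 0.336). AT1G13370, AT4G17070, AT4G19900 and AT2G27290 turned negative after scaling to a common median.

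The 12 named decreases kept their direction under quantile normalization, no scaling, median scaling and cyclic loess. AT3G47650, the Arabidopsis homologue of the Rubisco assembly factor BSD2, went from 6.51 ± 0.419 to 0.866 ± 0.0711, which is 7.51-fold lower in deposited intensity and a log2 difference of -3.40 (SE 0.11, adjusted p = 3.15e-07). PRK fell by 3.33 (SE 0.11) and PSAN fell by 2.64 (SE 0.16) on the log2 scale, and both were lower in deposited intensity, 7.61-fold and 7.57-fold. The sizes depend on the scaling, with -1.35 and -1.03 under cyclic loess and -6.85 and -6.86 under median scaling. AT1G24040 went from 2.96 ± 0.629 to 0.525 ± 0.0223, AT5G19210 from 2.32 ± 0.793 to 0.474 ± 0.0372 and AT1G64430 from 1.34 ± 0.179 to 0.342 ± 0.015. AT3G25410, a member of the bile acid and sodium symporter family, went from 0.864 ± 0.113 to 0.363 ± 0.0349. AT1G54500, a rubredoxin-like protein, went from 1.06 ± 0.155 to 0.487 ± 0.101. The log2 differences of AT1G33250, AT5G19540, AT3G15140 and AT3G15900 were -2.62, -2.60, -2.46 and -2.46.

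**Figure D3:**
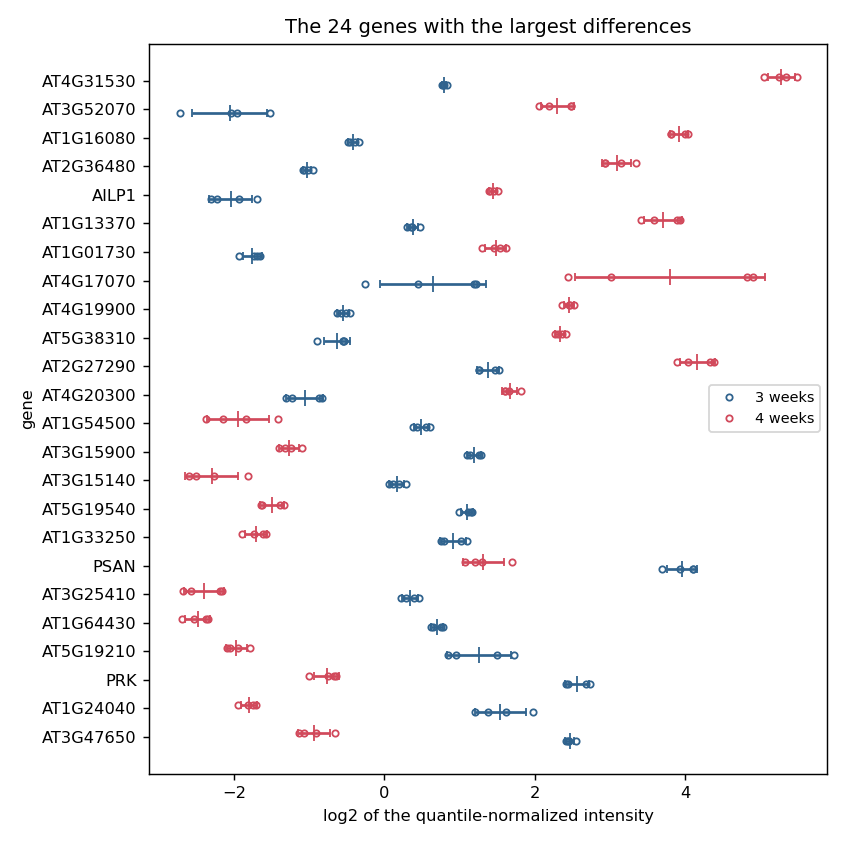
Log2 of the quantile-normalized intensity (horizontal) of the 12 genes with the largest increase and the 12 with the largest decrease at 4 weeks (vertical), with 1 circle per array, 3 weeks in blue and 4 weeks in red; vertical ticks are means and bars are SD over 4 arrays. In each of the 24 genes the 4 values of one age lie above the 4 of the other, a separation set by the rule that chose them; AT4G17070 has the widest bars.

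The photosynthesis genes came from 5 lists fixed beforehand and merged after the data were seen. NdhS and PSB27 of the closing section are on none of them. From these lists 6 genes were measured. Of these, 4 fell, 1 rose and 1 did not pass, and 5 were past the threshold adjusted over the list alone. LHB1B2, a chlorophyll-binding protein of the light-harvesting antenna, went from 73.5 ± 10.1 to 13.9 ± 1.7, a log2 difference of -1.52 (SE 0.11) that became 0.27 under cyclic loess. PSBY, a small protein of photosystem II, went from 6.82 ± 3.62 to 0.771 ± 0.636, a log2 difference of -3.96 (SE 0.82) with an adjusted p of 0.00501, which became 0.119 when replicates 1 and 2, and 3 and 4, were averaged first. PRK and PSAN are the other members that fell. PSBW, another small protein of photosystem II, rose from 17.5 ± 2 to 28.3 ± 1.23, a log2 difference of 1.74 (SE 0.07) that became -3.24 under median scaling. SBPASE, the sedoheptulose bisphosphatase of the Calvin cycle, was listed at 0 on 3 of 4 arrays of 3 weeks and on all 4 of 4 weeks, with 0.00689 on the remaining array. The median log2 difference of the 6 was -2.08, and limma camera gave an adjusted p of 0.105 (0.233 with an estimated correlation), so as a set they did not stand apart from the other genes. In fry, which does not compare with other genes, the p for movement in one direction was 5.82e-06. Camera's adjusted p was 7.06e-05 under no scaling, 0.00436 under median scaling and 0.873 under cyclic loess, where the median was -0.499. The 6 ranked high at 3 weeks, with a median rank percentile of 98.5. Of the 100 probes brightest at 3 weeks, 92 had a lower deposited mean at 4 weeks. Camera did not match genes on brightness, so its calls cannot tell a fall of these genes from a fall of bright probes in general.

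Of 39 plastid ribosomal proteins on the list, 6 were measured, of which 0 rose, 2 fell and 4 did not pass; the same 2 passed when adjusted over the list alone. AT3G54210, which encodes protein L17, went from 1.45 ± 0.69 to 0.757 ± 0.548, a log2 difference of -2.22 (SE 0.68, adjusted p = 0.0276). That call was lost in 5 of the 8 fits that left out 1 array, without scaling (adjusted p = 0.217), under cyclic loess (0.14) and with array weights (0.0787). AT4G01310, which encodes protein L5, had a log2 difference of -1.11 (SE 0.12, adjusted p = 0.000214), although its deposited intensity was 0.366 ± 0.107 at 3 weeks and 0.617 ± 0.0625 at 4 weeks and its difference without scaling was 0.77; under cyclic loess it did not pass (adjusted p = 0.101). The gene for protein L29, AT5G65220, had 0.391 ± 0.167 and 1.44 ± 0.187, and its log2 difference of 0.40 did not pass (adjusted p = 0.204). It passed with the replicate number as a block (0.0236), but not when replicates 1 and 2, and 3 and 4, were averaged first (0.461). Its call depends on the scaling, with 1.92 without scaling (adjusted p = 0.00104), 1.56 under cyclic loess (0.00796) and -1.95 under median scaling (0.000663). The remaining members, AT1G29070, AT3G13120 and AT1G64510, were listed at 0 on 3 of 4 arrays of 3 weeks. At 4 weeks AT3G13120 was above 0 on all 4 arrays, from 0.15 to 0.219, AT1G29070 was above 0 on 3 and AT1G64510 on 0. The log2 differences of these 3 lie near 0 because of the floor, which holds the list median near 0. For the list the median was -0.0312 and the mean -0.498; camera gave an adjusted p of 0.32 (0.347 with an estimated correlation), and fry a p of 0.0101 for one direction and 0.000242 for either direction. The median turned to 0.0111 without scaling and 0.0359 under cyclic loess, and was -0.975 under median scaling.

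Smaller lists had 1 to 3 measured genes each, and no list test was run on them. CHLM, PPDK, CCS and TPP2 lay below the floor used without scaling on every 3-week array, so no fall could show in that setting. Both measured genes of the list for chlorophyll and haem synthesis were lower at 4 weeks after normalization. AT1G74470, the geranylgeranyl reductase, went from 5.04 ± 0.111 to 1.80 ± 0.238, a log2 difference of -1.64 (SE 0.21) that became 0.16 under cyclic loess. CHLM, the magnesium protoporphyrin methyltransferase, had a log2 difference of -0.88 (SE 0.09) that became 1.06 without scaling, with deposited intensities of 0.204 ± 0.0295 and 0.551 ± 0.039. FATB, an acyl carrier protein thioesterase of plastid fatty acid synthesis, went from 0.369 ± 0.188 to 0.0189 ± 0.00518, a log2 difference of -2.59 (SE 0.21) with the same sign under every scaling, not past the threshold without scaling (-0.50, adjusted p = 0.198). FATB lay at the floor on all 4 arrays of 4 weeks, so the floor sets the size, which was -1.72 with the floor at the median probe and -6.14 among probes above 0 on all arrays. PPDK, pyruvate orthophosphate dikinase and the 1 measured gene of the senescence list, had a log2 difference of -0.77 (SE 0.21, adjusted p = 0.0167) that became 0.66 without scaling and did not pass with the replicate number as a block (0.0557). Its deposited intensity was 0.087 ± 0.0143 at 3 weeks and 0.421 ± 0.0834 at 4 weeks. It also counts, with PRK, among the 2 kinases by name, both lower at 4 weeks after quantile normalization.

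Of 3 chaperones by name, CCS, the copper chaperone for superoxide dismutase, had a log2 difference of -0.66 (SE 0.20, adjusted p = 0.0261), which became 0.25 without scaling, with deposited intensities of 0.0382 ± 0.0151 and 0.308 ± 0.0585. It did not pass with the replicate number as a block (adjusted p = 0.0599) or in 5 of the 8 fits that left out 1 array. The chaperonin subunits Cpn60beta4 and Cpn60beta3 did not pass, with log2 differences of 0.25 (SE 0.23) and 0.33 (SE 0.27), and passed without scaling, with 0.46 and 0.90. Without scaling both lay below the floor on every 3-week array, so only a rise could show there. Of 2 proteases by name, TPP2, tripeptidyl peptidase, had a difference of -0.91 (SE 0.24, adjusted p = 0.0142), which became 0.67 without scaling and did not pass with the block (0.0726), with deposited intensities of 0.113 ± 0.0369 and 0.425 ± 0.0903. SPPA did not pass, with -0.23 (SE 0.13), except when replicates 1 and 2, and 3 and 4, were averaged first (adjusted p = 0.0217). The lists fixed by locus hold chosen genes and not every gene of a kind, and 13 of the 20 had no measured member. These cover photosynthetic electron transport with ATP synthase, photorespiration, plastid isoprenoids, plastid transcription, plastid proteases and chaperones, plastid protein import, starch and sugar, nitrogen with sulfur and amino acids, antioxidant enzymes, defence with jasmonate, flavonoids, and markers of flowers and of roots. No symbol or synonym matched 7 of the 10 lists fixed by name or prefix, those for the plastid genome, the mitochondrial genome, ribosomal proteins, pentatricopeptide repeats, transporters, transcription factors and tRNA ligases. Genes of these kinds can still be on the arrays under other names, as the plastid ribosomal proteins are. Whether RNA of other organs differed between the ages could therefore not be read from the markers.

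Some genes were listed at 0 at one age only. This held for 288 probes, 72 of them with 1 gene, that were at 0 on all 4 arrays of 3 weeks and above 0 on all 4 of 4 weeks, and for 10 probes, 1 with 1 gene, the other way round. AT4G24090 had intensities of 1.81, 1.80, 1.74 and 1.78 on the 4 arrays of 4 weeks. DRT101, a phosphoacetylglucosamine mutase, had 1.45, 1.47, 1.54 and 1.55. AT5G63390, the 1 gene at 0 on all 4 arrays of 4 weeks and above 0 on all 4 of 3 weeks, had 0.0055, 0.0385, 0.0408 and 0.0377 at 3 weeks. No fold is given for these genes.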

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

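The tests of row register, dim probes, monotone scaling and background, the test of the effect shared by both ages and the test of the photosynthesis names were chosen only after the results they bear on were seen. A sample far from the others was found in 5 of the 90 groups of 4 arrays examined for named genes and array totals, where chance gives about 4.5. The gaps of these 5 were taken on the log2 scale after normalization, not on the deposited intensities printed beside them. For AT5G38310 at 3 weeks the gap of replicate 2 took up 0.946 of the range, with an intensity of 0.195 against 0.296, 0.291 and 0.313 on the other arrays. For PSBW at 3 weeks the gap of replicate 3 took up 1 of the range after normalization, with an intensity of 15.1 against 18.1, 19.9 and 17.0, the last 3 having almost the same rank on their arrays. For LHB1B2 at 3 weeks the gap of replicate 2 took up 1 of the range, with 88.6 against 69.7, 66.4 and 69.3. For CCS at 3 weeks that of replicate 3 took up 0.915, with 0.0164 against 0.0401, 0.047 and 0.0494. For NdhS at 3 weeks that of replicate 4 took up 0.965, with 0.97 against 0.893, 0.906 and 0.85.

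Of all probes 56.6% passed the test between the ages. Of the 35 splits of the 8 arrays into 4 and 4, only the real one gave 1946 calls. The others gave 9 at most. This test takes the arrays as exchangeable. The likeness of replicates 1 and 2, and of 3 and 4, and a possible pairing by number go against that. The test therefore cannot exclude chance by itself. The 8 splits that part all 4 number pairs gave 1 call at most besides the real one and the 3 that keep replicates 1 and 2, and 3 and 4, whole gave 9, both too few for a share under 0.05, while fits with the number as a block and with these replicates averaged gave 1843 and 1544 calls. Noise of dim probes and a scaling that keeps the order of probes are argued against by rank correlations. Over probes above 0 on all arrays the highest Spearman correlation between ages was 0.304, against 0.903 or more within an age. Over the 300 probes brightest at 3 weeks the correlation between ages was 0.46. At 3 weeks it was 0.932 between the mean ranks of replicates 1 and 2 and those of 3 and 4. The 300 were chosen on the 3-week arrays, which favours the 0.932, so that gap cannot decide by itself. A shift of all rows at one age is excluded by the correlation of mean ranks. It was 0.475 at the true rows and at most 0.0582 at any of 3438 row shifts. In each of 12 blocks of probe numbers it was 0.407 or more, which argues against a whole block out of register. A misplaced stretch within a block was not tested. Background or hybridization that differed between the ages cannot be told apart from a change of the transcripts with age, which stays open and untested. On every 3-week array 288 probes were at 0 that were above 0 on every 4-week array. The labels do not say how the samples of either age were hybridised.

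Replicates 1 and 2, and replicates 3 and 4, went together at both ages, and an effect of the spots on the arrays or their hybridization may contribute. The difference between the replicate pairs, over 1388 probes, correlated at 0.176 between the ages, against at most 0.089 in 1000 shuffles. Of its variance 7.7% lay between runs of 96 probe numbers, against at most 5.67% in 1000 shuffles, so position on the array may carry part of it. AT4G17070 is an example, with 19.7, 18.6, 5.99 and 4.15 at 4 weeks. Shared plant material of each replicate pair stays open and was not tested.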

How the results depend on the processing

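The number of probes past the threshold lay between 1544 and 1993 under every alternative that kept all probes and arrays, was 1383 of 1840 among probes above 0 on all arrays, and lay between 1830 and 1892 when 1 array was left out. Without normalization, but with values raised to a floor, 1710 were higher and 263 lower, and the median difference over all probes was 0.408. After median scaling 688 were higher and 1160 lower. With the replicate block 1843 passed, PPDK, CCS and TPP2 lost their calls (adjusted p = 0.0557, 0.0599 and 0.0726), AT5G65220 gained one (0.0236), and no other of the 43 genes tested under the alternatives changed its call, nor did either list. Averaging replicates 1 and 2, and 3 and 4, ended 7 calls, among them PSBY, AT4G17070 and AT3G54210 (0.119, 0.123 and 0.224), and gave SPPA one (0.0217).

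Median scaling turned AT1G13370 to -0.44, AT4G17070 to -0.94, AT4G19900 to -0.08, AT2G27290 to -1.56, PSBW to -3.24, NdhS to -2.14 and AT5G65220 to -1.95, and ended the calls of AT4G31530, AT5G38310, AT4G20300 and CCS. Without normalization AT4G01310 turned to 0.77, CHLM to 1.06, PPDK to 0.66, CCS to 0.25 and TPP2 to 0.67. CHLM, PPDK, CCS and TPP2 lay below the floor of that setting on every 3-week array, so no negative difference was possible for them. Cyclic loess turned LHB1B2 to 0.27, AT1G74470 to 0.16, Cpn60beta4 to -0.02, Cpn60beta3 to -0.44, SPPA to 0.04 and PSB27 to 0.27. CCS turned to 0.09 among probes above 0 on all arrays and Cpn60beta3 to -0.15 with replicates 1 and 2 alone. AT3G54210 lost its call without replicates 1, 2 or 3 of 3 weeks or 3 or 4 of 4 weeks (adjusted p from 0.0545 to 0.0725), and CCS without 1, 2 or 4 of 3 weeks or 3 or 4 of 4 weeks (0.0559 to 0.0699). The causes were not tested.

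For plastid ribosomal proteins the median turned from -0.0312 to 0.0111 without normalization and 0.0359 under cyclic loess, was -0.975 under median scaling, -1.11 without the dimmest probes and -0.881 among probes above 0 on all arrays, and lay between -0.0756 and 0 with 1 array left out; fry passed where camera did not. For photosynthesis genes camera passed at -2.66 without normalization and -6.59 after median scaling but not under cyclic loess (-0.499, adjusted p = 0.873), and with an estimated correlation passed without normalization (0.0444) and not under median scaling (0.192), fry passed at -2.08, and the median lay between -2.22 and -1.98 with 1 array left out. A variance trend in camera changed neither call. Floors at percentiles 1 and 10 could not be run, quantile normalization is already the setting used, and camera without a shared variance prior and robust camera were not run. Values near 0 limit what can be read from dim probes.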

Other observations

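LAS, a GRAS regulator of axillary meristems, went from 0.00701 ± 0.0062 (SD, n = 4) at 3 weeks to 2.19 ± 0.233 at 4 weeks, a log2 difference after normalization of 3.82 (SE 0.18) with a limma adjusted p of 2.2e-06 and the same sign under every scaling. NdhS, a subunit of the chloroplast NADH dehydrogenase-like complex, went from 0.905 ± 0.0495 to 3.14 ± 0.295, a difference of 1.33 that became -2.14 under median scaling. HEMA3, a glutamyl-tRNA reductase, went from 1.49 ± 0.222 to 0.70 ± 0.389, a difference of -2.29 (SE 0.44, adjusted p = 0.00371) with the same sign under every scaling, not past the threshold when replicates 1 and 2, and 3 and 4, were averaged first (0.106). PSB27, a lumenal protein of photosystem II, had 2.29 ± 1.64 and 1.57 ± 1.15 and a difference of -1.26 (SE 0.86) that did not pass (adjusted p = 0.268). PSB27 differed between the replicate pairs, and it passed with these as a block (0.0138), within replicates 1 and 2 (-0.55, 0.00836), within 3 and 4 (-1.95, 0.0119) and under median scaling (-4.50, 0.00379), while it did not pass with the pairs averaged first (0.535) and cyclic loess gave 0.27 (0.766). These genes were chosen after their values were seen.

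Among the 72 named genes listed at 0 on every 3-week array, LpxA, an acyltransferase of lipid A synthesis, had intensities from 0.724 to 0.898 at 4 weeks and GH9B16, a glycosyl hydrolase, from 0.657 to 0.716. The 100 brightest probes of each age shared 37, where independent lists would share 2.91. Of the 100 brightest at 3 weeks, 92 had a lower deposited mean at 4 weeks, and of the 100 brightest at 4 weeks, 71 had a higher one, as had 2680 of all 3439 probes. Choosing probes as bright at one age favours a lower value at the other. The 6 probes at the ceiling on all arrays of 3 weeks had intensities from 21.7 to 44.9 at 4 weeks, and the 3 at the ceiling on all arrays of 4 weeks had 7.12 to 91.1 at 3 weeks; none of the 9 has a single listed gene.

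Probes whose number is a multiple of 6 were dim. Of these 261 probes, 119 have at least 1 listed gene, and AT1G64510 of the plastid ribosomal list is on one of them. Whether those names belong to the spots was not tested. Leaving out 1 stretch of the numbering, chosen after the values were seen, 0% of 215 such probes were above 0 on all 8 arrays, against 57.4% of the 3178 other probes and 37% of the 46 inside that stretch, and 17 of the 261 passed the test between ages.

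The photosynthesis genes of the merged list ranked high on the arrays, which bears on whether the gene names belong to the rows. The median rank percentile of the 6 was 98.5 at 3 weeks and 88.9 at 4 weeks. Of 10000 random lists of 6 named genes, 0% had a median as high at 3 weeks and 0.39% at 4 weeks. This argues against names unrelated to the rows for the set, which was merged after the data were seen. A median cannot show that each name belongs to its row. SBPASE, at or near 0 on all arrays, stands apart from the other 5. No biological explanation was tested.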
